A study of Homo sapiens with 10 samples.

How the data were processed

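The series holds 10 chromatin immunoprecipitation sequencing samples of purchased human primary liver sinusoidal endothelial cells (LSEC), the fenestrated endothelium that lines the hepatic sinusoids. The cell type is given as labelled and was not checked by another assay here. Per the labels' protocols, cells were kept without serum for 2 h and then received tumour necrosis factor alpha (TNF) or control treatment for 90 min. Chromatin was cut with micrococcal nuclease and sonication and precipitated with antibodies to acetylated lysine 27 of histone H3 (H3K27ac) or to the transcription factor NF-kB. Groups and replicate numbers were taken from the sample titles. Peak lists of 5 libraries were used: 2 H3K27ac control, 2 H3K27ac TNF and 1 NF-kB TNF library. The 4 input libraries and the NF-kB library of control cells were not analysed here, so NF-kB has no untreated comparison.

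The reads were processed by the authors. CASAVA 1.4, Bowtie2 and MACS2 with genome build hg38 are named in the submitters' processing notes, and settings and other versions are not given in the sources used here. Each deposited peak list has 1 line per peak with its position and 1 score. Peaks were called by the authors in each library separately, not on pooled samples, as the 1 list per library shows. The deposited score was read as a −log10 of a p or q value, from the values themselves, whose minimum lies just above 2 in each list. Whether it is p or q, and whether the input served as the background of the peak calls, is not given in the sources used here. This score belongs to the peak in its own library and was used only to rank or filter peaks within a list. The lists hold chromosomes 1 to 22 and X. They hold no read counts, so the sequencing depth is unknown and no interval for depth can be given. The number of peaks and the length they cover are given in its place. A peak list shows where signal passed the authors' threshold, so a longer covered length can come from stronger signal, wider signal or deeper sequencing.

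The measured quantity was therefore the length of sequence, in bp, covered by called peaks. All H3K27ac peaks of the 4 libraries were merged, and merged regions 12500 bp or less apart were stitched into 26486 domains, the distance commonly used for super enhancers. The covered length of each library in each domain was taken as log2(bp + 500), centred on the median of the tested domains of that library, and tested with limma 3.58.1 (trend, moderated) in R 4.3.3 with Benjamini-Hochberg adjustment at 5%. The 9292 domains with a mean covered length of at least 2000 bp were tested. A log2 change on this scale understates the change where little is covered. The same fit was made for 19974 protein-coding genes over the gene span with 50 kb either side, of which 15170 had a mean of at least 1000 bp. Gene positions came from a RefSeq table of assembly GRCh38.p14, the same build. That table gives no strand, so the whole span stood in for the planned 5′ end, and the nearest gene was the gene whose span overlaps a domain or lies closest. Neighbouring genes share windows, so counts of genes are not independent, and the number of windows that do not overlap is given for the lists where it matters most.

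Before the data were examined, 17 gene lists with 229 genes, the tests, the alternatives and the rule for named genes were fixed. The rule names the 15 domains with the largest rise and the 10 with the largest fall among those past 5%, the 10 gained and 10 lost regions with the highest score percentile within their own lists, the 15 NF-kB peaks with the highest deposited score, and members of the lists, those past 5% first, with a fixed set always eligible. All 229 list genes were found in the table. Lists were tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation. Each list's members were also adjusted over the list alone. The domains described as long are an addition made after the data were seen: the 500 domains with the longest mean covered length, a size range like that of super enhancers, which were not ranked by signal because signal is not in the lists.

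A merged region was called gained when both TNF libraries and neither control library had a peak overlapping it by at least 1 bp, and lost in the reverse case. Shared regions had a peak in each of the 4 libraries. The counts were set beside those of the other 2 ways to split 4 libraries into equal pairs. With 2 libraries against 2, no exact permutation test of a single value can give a p below 0.333. Similarity of peak sets was the Jaccard index in bp. Shares of regions, domains and genes with an NF-kB peak were compared with two-sided Fisher exact tests, using as background the genes with at least 1 merged region in the window. Intervals are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for the plots.

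The fits were tested on simulated data with 200 changed items, made from the mean of each item and independent normal noise of the fitted spread. Such data meet the assumptions of the fit and hold no shared windows or offsets between libraries. They check the code and do not give the error rate in the real libraries. Of simulated log2 changes of 0.5 and 1, 73% and 99% were recovered in domains, with 13 false calls, and 70% and 96% in genes, with 7 false calls. Covered lengths were checked in 200 interval trials with 0 wrong lengths. The alternatives were the replicate number as a block, pseudocounts of 100 and 2000 bp, no centring, quantile normalization, no minimum length, the higher-scoring 50% of each list, equal numbers of top peaks, each library left out in turn, stitching at 5000 bp or none, gene ends left out with 2500 bp either side, gene windows of 10 and 100 kb, and peaks covering at least 50% of a region. Comparisons of NF-kB peaks within classes of domain length and region width, pooled as Mantel-Haenszel odds ratios, were added after the data were seen. When a library is left out, the lone library of its group is assumed to vary like the other group. A search for the NF-kB motif in the peaks needs a genome sequence and was not run.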

Results

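H3K27ac, a mark of active enhancers and promoters, was profiled in primary LSEC after 90 min of TNF or control treatment with 2 libraries per group, and NF-kB was profiled in 1 library of TNF-treated cells. Control replicates 1 and 2 had 109377 and 105977 H3K27ac peaks covering 81.3 and 67.3 Mb. TNF replicates 1 and 2 had 106145 and 105250 peaks covering 77.0 and 75.7 Mb. The group means, 74.3 Mb ± 9.95 (SD, n = 2) in control and 76.4 Mb ± 0.948 in TNF cells, differed by less than the control spread. The NF-kB library had 1153 peaks with a median width of 179 bp, covering 0.230 Mb. No label says that replicates came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical. Peak sets overlapped more within groups, with a mean Jaccard index of 0.668, than between groups, with 0.594, a difference of 0.0741. The exact permutation p was 0.333, the smallest that 3 splits allow.

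To find where TNF changed acetylation, the H3K27ac peak length in stitched domains was compared between TNF and control libraries. H3K27ac rose over the domain at TNFAIP3, which encodes the NF-kB inhibitor A20 (chromosome 6, 137693133 to 137905574, hg38), from 32.9 kb ± 4.99 (SD, n = 2) in control to 117 kb ± 6.07 in TNF cells. The domain at CXCL8, the gene of a neutrophil-attracting chemokine (chromosome 4, 73659026 to 73746933), rose from 22.6 kb ± 3.82 to 50.5 kb ± 0.642. H3K27ac fell over the domain at JUN, an AP-1 transcription factor gene (chromosome 1, 58724958 to 58787206), from 24.5 kb ± 2.40 to 17.5 kb ± 0.728. Of 9292 domains tested with limma, 1799 rose and 1722 fell at an adjusted p of 5%. The median log2 change was 0.58 among those that rose and fell by 0.51 among those that fell.

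The domains with the largest rises carried little or no called H3K27ac in control cells. A domain within ZFAND3 (chromosome 6, 38110618 to 38139586) rose from 0.136 kb ± 0.192 to 9.29 kb ± 0.279, a log2 change of 3.96 (SE 0.190, limma adjusted p = 9.72e-12). Domains within PSD4 and PAX8, within NNT, and 33.3 kb from CCN6 had no called peak in either control library and 5.03 kb ± 0.445, 4.10 kb ± 0.0530 and 4.51 kb ± 0.130 in TNF cells (SD, n = 2). Domains in PRORP, VPS41, TNFAIP8, TM9SF4, PTK2 and NRXN3 rose by log2 changes of 3.54, 3.30, 3.24, 2.93, 2.91 and 2.80. The domain 20.4 kb from RIPK2, which encodes a kinase of NOD receptor signalling, rose by 2.89. Intergenic domains rose by 3.30 at 57.2 kb from SUGCT, 2.80 at 165 kb from ATP2B1, 2.78 at 725 kb from GOT2 and 2.74 at 56.8 kb from CLDN16, the nearest genes. The domain next to SUGCT held 3 NF-kB peaks, those in PRORP and TM9SF4 and near CLDN16 held 1 each, and the others with the largest rises held none. The largest fall was in PITPNM3, from 5.19 kb ± 0.490 to 0.639 kb ± 0.904 (log2 change −2.61, SE 0.35, limma adjusted p = 7.20e-06). ZNF395 fell from 15.5 kb ± 2.88 to 2.73 kb ± 0.332, and MXI1, which encodes an antagonist of MYC, from 4.52 kb ± 0.704 to 0.687 kb ± 0.276. Domains at MTSS2 and VAC14, SLC1A7 and COL5A1, a collagen gene, had log2 changes of −2.04, −1.99 and −1.96. Intergenic domains whose nearest genes were LOC124903470, GJA1, NT5C1B-RDH14 and TNS3, each more than 100 kb away, had −2.49, −2.04, −2.02 and −1.98. None of the 10 domains with the largest falls held an NF-kB peak, which says little, since only 4.12% of the domains that did not pass held one.

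Among the 500 longest domains, each averaging at least 19.5 kb, 199 rose and 80 fell. Rising was more frequent among them than among the other domains (odds ratio 2.97, Fisher exact p = 1.18e-27), in a comparison chosen after the data were seen. That ranking used the TNF libraries too, so a rise helped a domain to enter. Among the 500 longest in the control libraries alone, 154 rose and 108 fell. The odds ratio was 1.93 for rising (Fisher exact p = 3.33e-10) and 1.23 for falling (Fisher exact p = 0.0757). The SE was 0.0457 for the longest domain, at CRIM1 and FEZ2, against 0.190 for the domain within ZFAND3. Long domains could thus pass at smaller changes, and these odds ratios do not separate more frequent rises from higher precision. Besides TNFAIP3 and CXCL8, long domains rose at PDE5A (log2 change 1.74), IRAK2 with TATDN2 (1.71), LPP (1.20), TMCC2 with NUAK2 (1.12) and TBC1D1 with LOC124900692 (1.10). HBEGF with PFDN1 rose by 0.98 and ADHFE1 with VXN by 0.96. Rises at PTX3 with VEPH1 (0.86), HIVEP2 (0.85), LHFPL2 (0.85), ADAMTS12 (0.82) and IRF1 (0.79) were smaller. The domain at GPX3, ANXA6 and TNIP1, whose product binds A20, rose from 11.1 kb ± 2.58 to 30.3 kb ± 1.10 (SD, n = 2). IRAK2 is a kinase of interleukin receptor signalling. Long domains fell 1.29 kb from CD200R1L (−0.60) and at HSF2BP with RRP1B (−0.57), NCAM2 (−0.51), ME3 (−0.50) and ITGB5 (−0.48). Smaller falls were at SEC14L1 (−0.42) and FKBP5 (−0.41), which encodes a co-chaperone of the glucocorticoid receptor. Neither SEC14L1 nor FKBP5 passed without centring (limma adjusted p = 0.0670 and 0.0919). The domain with the longest mean covered length, at CRIM1 and FEZ2, had a log2 change of 0.22 that passed, but not without TNF replicate 2 (adjusted p = 0.0562), without centring (0.326) or with quantile normalization (0.725). That at COL3A1 and COL5A2 had 0.16 and passed, but not without TNF replicate 1 (adjusted p = 0.0878), TNF replicate 2 (0.104) or centring (0.498), and had −0.017 with quantile normalization. The long domain 50.8 kb from MYC measured 120 kb ± 12.5 in control and 130 kb ± 0.182 in TNF cells and did not pass (log2 change 0.11, limma adjusted p = 0.0629), but passed without control replicate 2 (adjusted p = 0.0426) and with no minimum length (0.0192). Without centring, 1234 domains rose and 869 fell. With no stitching 741 rose and 462 fell, with the higher-scoring 50% of each list 1106 and 893, and with no minimum length 3552 and 2327.

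The series title names chemokine production, so the CXC chemokine cluster at 4q13.3 was examined (chromosome 4, 73690569 to 74149195, hg38), from 50 kb before CXCL8 to 50 kb after CXCL2. Its 6 listed members, CXCL8, CXCL6, CXCL1, CXCL5, CXCL3 and CXCL2, encode chemokines that attract neutrophils. Called H3K27ac over the 459 kb measured 49.6 and 40.7 kb in the control libraries and 98.6 and 95.5 kb in the TNF libraries. The means were 45.1 kb ± 6.28 and 97.0 kb ± 2.18 (SD, n = 2), a ratio of 2.15, with an exact permutation p of 0.333, the smallest possible. The cluster held 5 NF-kB peaks. The peak with the highest score of the whole list, 123 in the authors' own per-peak value, lay at the lower-coordinate end of CXCL8 (73740374 to 73740707). Others lay 14.3 and 32.6 kb from CXCL8, across the lower-coordinate end of CXCL1, and 0.0290 kb from CXCL2.

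**Figure D1:**
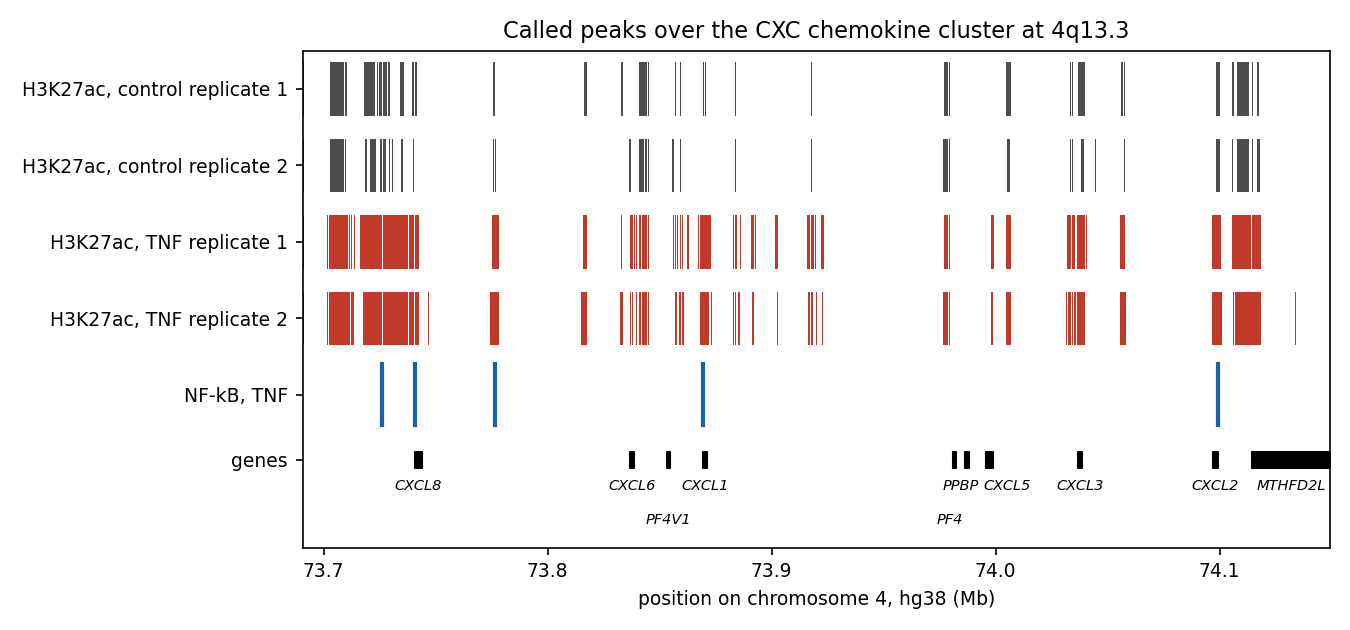
Called H3K27ac peaks in 2 control (grey) and 2 TNF (red) libraries, centres of NF-kB peaks (blue, width not to scale) and gene spans (black) along chromosome 4 in Mb of hg38. Peaks cover 49.6 and 40.7 kb in the control libraries and 98.6 and 95.5 kb in the TNF libraries.

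To group the changes by gene function, H3K27ac was compared in windows of 50 kb around protein-coding genes. A gene is said to rise or fall where the peak length in its window did. CCL2, the gene of a monocyte-attracting chemokine, rose from 5.60 kb ± 0.514 (SD, n = 2) to a mean of 24.0 kb in TNF cells, a ratio of 4.28. IL1B, which encodes interleukin-1 beta, rose from 9.77 kb ± 1.61 to 39.1 kb ± 1.68. NFKBIA, which encodes the inhibitor IκBα, rose by a ratio of 2.01 from 10.9 kb ± 0.943 (log2 change 0.99, SE 0.0791). Of 15170 genes tested with limma, 2690 rose and 2725 fell. Without centring 1460 rose and 1347 fell, and with windows of 10 kb 1677 and 1535. Of 115 list members that rose or fell, 13 had 0 kb of H3K27ac in the gene span with 2 kb either side in any library, so their change lay in flanking sequence. The call was kept by 91 of the 115 with each library left out in turn, and by 69 in all alternatives in which they were tested.

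All 6 CXC chemokines of the chromosome 4 cluster rose, from a log2 change of 0.88 at CXCL5 to 1.24 at CXCL1, and 6 rose adjusted over the list alone. Their windows form 2 groups that do not overlap. The list rose with limma camera (adjusted p = 1.23e-09), and had adjusted p = 0.175 with an estimated correlation. Of 9 other inducible chemokines tested, 4 rose, namely CCL2 (2.02), CCL7 (2.03), CCL5 (2.24) and CCL8 (1.55), and 7 rose adjusted over the list alone. The windows of these 4 form 2 groups that do not overlap, and the spans of CCL5, CCL7 and CCL8 with 2 kb either side held 0 kb of H3K27ac in both groups. The list rose (camera adjusted p = 2.02e-05, and adjusted p = 0.394 with an estimated correlation). CXCL9, CXCL10 and CXCL11 share peaks and each measured 2.70 kb ± 0.127 in control and 3.61 kb ± 0.0240 in TNF cells (limma adjusted p = 0.0550, and as low as 0.0324 in other settings, with quantile normalization). CX3CL1 had no called peak in its window in control cells and was not tested.

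Of 22 NF-kB subunits and feedback regulators, 18 rose and none fell, with the same count of 18 adjusted over the list alone (camera adjusted p = 1.07e-14, and adjusted p = 0.175 with an estimated correlation). They included TNFAIP3 (log2 change 1.56), BIRC2 (1.46), BIRC3 (1.43) and TNIP1 (1.44). The subunit gene NFKB1 rose by 1.28, whereas RELA (0.08), NFKBIB (−0.05), REL and RELB did not pass. REL measured 3.45 kb ± 0.858 in control and 3.32 kb ± 0.494 in TNF cells, and RELB 5.06 kb ± 0.691 and 5.04 kb ± 1.30 (SD, n = 2). Of 21 cytokine and growth factor genes, 18 rose and none fell, also 18 adjusted over the list alone (camera adjusted p = 7.33e-14, and adjusted p = 0.175 with an estimated correlation). The largest changes were at IL1A (2.65), CSF2 (2.04) and IL1B (1.97), and IL6 rose by 0.65. PDGFB and VEGFC, which rose, had log2 changes of −0.22 and −0.038 with windows of 10 kb. EBI3 did not pass without control replicate 1 (adjusted p = 0.0648), control replicate 2 (0.113) or TNF replicate 1 (0.351), nor IL33 without control replicate 2 (0.0589), nor PDGFB without control replicate 2 (0.151) or TNF replicate 2 (0.124). Of 18 interferon response genes, 11 rose, or 13 with 1 that fell when adjusted over the list alone (camera adjusted p = 5.31e-05, and adjusted p = 0.259 with an estimated correlation). The 11 windows form 7 groups that do not overlap, and those of the 18 cytokine genes form 15. IFI6 (1.39), GBP2 (1.12) and GBP1 (0.90) had the largest changes of the interferon list, and IRF9, which rose, had −0.051 with windows of 10 kb. IFIH1 did not pass without control replicate 1 (adjusted p = 0.134) or TNF replicate 1 (0.0841), nor IFIT1 without control replicate 2 (0.0618), nor MX1 without TNF replicate 2 (0.138).

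Of 7 leukocyte adhesion genes tested, 4 rose, in 2 groups of windows that do not overlap, and 4 adjusted over the list alone. ICAM1 rose from 9.31 kb ± 1.82 to 16.4 kb ± 0.788 (SD, n = 2), and VCAM1 rose by a ratio of 1.61 from 9.31 kb ± 0.682. ICAM4 and ICAM5, next to ICAM1, rose by 0.77 each, and ICAM5 had −0.35 with windows of 10 kb. SELE, the gene of E-selectin, measured 0.584 kb ± 0.163 in control and 0.366 kb ± 0.517 in TNF cells, too little to be tested. The list rose (camera adjusted p = 0.00993, and adjusted p = 0.384 with an estimated correlation), and did not pass with windows of 10 kb (adjusted p = 0.829) or no minimum length (adjusted p = 0.0573). Of 16 immediate early and stress transcription factors, 7 rose and 2 fell, or 8 and 2 adjusted over the list alone. IRF1 rose by 0.96, while JUN fell by 0.52 and FOS by 0.49, the latter with an adjusted p of 0.0840 without TNF replicate 2 and JUN with 0.0824 with windows of 10 kb. BHLHE40 did not pass without control replicate 1 (adjusted p = 0.191), TNF replicate 1 (0.220) or TNF replicate 2 (0.0746), nor ETS2 without control replicate 2 (0.115). That list's camera adjusted p of 0.0244 became adjusted p = 0.374 with an estimated correlation, 0.0580 without TNF replicate 1, 0.0602 without TNF replicate 2, 0.138 without centring, 0.0942 with quantile normalization and 0.0548 with the higher-scoring 50% of each peak list.

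**Figure D2:**
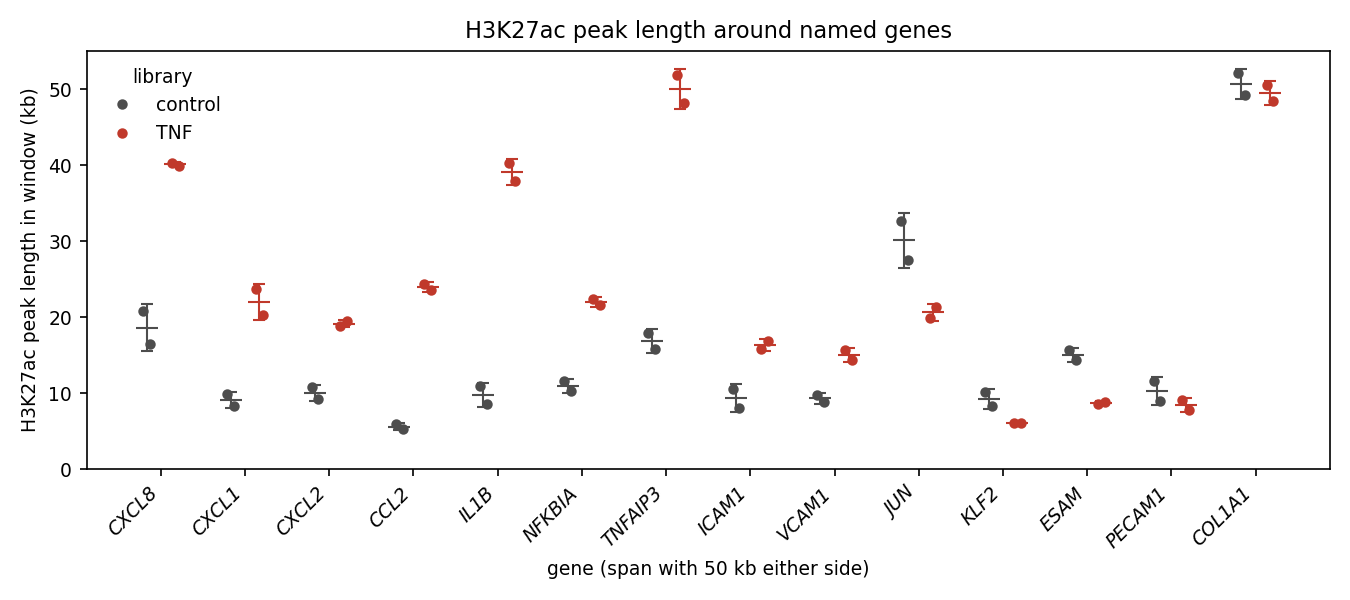
H3K27ac peak length in kb in the window of 14 genes, with points for the 2 libraries of each group and bars for the mean ± SD. CCL2 goes from 5.60 to 24.0 kb and IL1B from 9.77 to 39.1 kb, whereas KLF2 goes from 9.21 to 6.04 kb and COL1A1 has 50.7 and 49.5 kb.

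Endothelial genes moved in both directions. Of 5 shear stress and anti-inflammatory endothelial genes tested, 4 fell and 1 rose, with the same counts adjusted over the list alone. KLF2, a flow-induced transcription factor gene, fell from 9.21 kb ± 1.35 (SD, n = 2) to 6.04 kb ± 0.0509. NOS3, which encodes endothelial nitric oxide synthase, fell by 0.34, THBS1 by 0.40 and NHERF2 by 0.64 on the log2 scale, and CYP1B1 rose by 0.77. NOS3 did not pass without control replicate 2 (adjusted p = 0.139) or TNF replicate 1 (0.0749), nor THBS1 without control replicate 1 (0.0962) or TNF replicate 2 (0.0532). The list as a whole did not pass (camera adjusted p = 0.148), but passed as lower with windows of 10 kb (adjusted p = 0.0212). Of 20 pan-endothelial identity genes, 4 rose and 5 fell, or 4 and 6 adjusted over the list alone. TEK (0.72), FLI1 (0.55), CDH5 (0.51) and ETS1 (0.34) rose, and EGFL7 (−1.05), MMRN2 (−0.90), ESAM (−0.73), FLT1 (−0.60) and VWF (−0.50) fell. The span of EGFL7 with 2 kb either side held 0 kb of H3K27ac in both groups, so its fall lay in flanking sequence. FLT1 did not pass without control replicate 1 (adjusted p = 0.0953), control replicate 2 (0.0599) or TNF replicate 2 (0.0598), and MMRN2 had a log2 change of 0.10 with windows of 100 kb. PECAM1 (−0.25) and ERG (0.17) did not pass, although PECAM1 did without TNF replicate 1 (adjusted p = 0.0251) and other settings gave as low as 0.0113 for PECAM1 and 0.00256 for ERG, both with windows of 100 kb, and the list had a camera adjusted p of 0.808. Of 13 Notch and sprouting genes, 5 rose and 4 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.333). ESM1 (1.15), ANGPT2 (0.71) and HEY2 (0.64) rose. JAG1 (−0.38), a Notch ligand gene, fell, as did JAG2 (−0.72), which had an adjusted p of 0.0680 without control replicate 1. HES1 did not pass without control replicate 1 (adjusted p = 0.260) or TNF replicate 2 (0.35), nor NOTCH1 without control replicate 2 (0.0705) or TNF replicate 2 (0.260). HEY2 and JAG2 changed in flanking sequence alone. Other settings also ended calls, with the highest adjusted p at KLF2 and VWF with the higher-scoring 50% of each peak list (0.384 and 0.0503), NOS3 and FLT1 with windows of 100 kb (0.436 and 0.578), THBS1 with windows of 10 kb (0.17), and ETS1 and JAG1 without centring (0.156 and 0.0738).

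Of 13 liver sinusoidal markers tested, 2 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.499). LYVE1 (0.28) and FCN3 (0.28) rose in flanking sequence alone. LYVE1 did not pass without control replicate 1 (adjusted p = 0.127) or TNF replicate 1 (0.184), nor FCN3 without control replicate 2 (0.303) or TNF replicate 2 (0.296), and FCN3 had −0.23 with windows of 10 kb. FCN2 (−1.66), MRC1 (−0.64) and STAB2 (−0.62) fell, FCN2 and STAB2 in flanking sequence alone, and STAB2 did not pass without control replicate 1 (adjusted p = 0.206) or TNF replicate 2 (0.121). Of 11 stellate and other mesenchymal markers, ACTA2 (0.57), PDGFRA (0.53), LUM (0.51) and DCN (0.37) rose and DES, in flanking sequence alone, fell by 0.38, with adjusted p from 0.0524 to 0.159 for DES when any 1 library was left out. The counts were 4 and 1 adjusted over the list alone (camera adjusted p = 0.159). COL1A1, COL1A2 and COL3A1, the fibrillar collagen genes, had log2 changes of −0.02, −0.02 and −0.01 and did not pass. The name LSEC follows the labels. In control cells, gene spans with 2 kb either side held a median of 16.6 kb of H3K27ac for the 12 mesenchymal markers, 1.96 kb for the 22 pan-endothelial genes and 0 kb for the 16 liver sinusoidal markers. Of 9 hepatocyte markers, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.490). SERPINA1 rose by 1.80, and APOA1 and APOC3, whose windows hold the same peaks, fell by 0.42, with 0 kb in the span of APOC3. Of 8 macrophage and blood cell markers, LYZ, in flanking sequence alone, rose by 0.54 and CD79A fell by 0.39, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.855), and neither passed without control replicate 2 (adjusted p = 0.0813 and 0.107), nor LYZ without TNF replicate 1 (0.152), nor CD79A without control replicate 1 (0.134) or TNF replicate 2 (0.470). That list had a median log2 change of 0.04, a mean of −0.01 and a camera direction of lower. Of 4 cholangiocyte markers, CFTR fell by 1.37 and KRT7 by 0.35, also 2 adjusted over the list alone (camera adjusted p = 0.159), but with windows of 10 kb KRT7 was higher in TNF cells, with a log2 change of 0.31 that did not pass (adjusted p = 0.171). Of 3 lymphatic markers, RELN rose by 0.46 (adjusted p = 0.116 without TNF replicate 1), also 1 adjusted over the list alone (camera adjusted p = 0.490). Of 12 housekeeping genes, 3 rose, YWHAZ by 0.85 at most, and HPRT1 fell by 0.81, with 3 and 1 also adjusted over the list alone (camera adjusted p = 0.405). B2M, which rose, had adjusted p from 0.0599 to 0.163 when any 1 library was left out, and PPIA, which rose, had 0.107 without control replicate 2 and a log2 change of −0.23 with windows of 10 kb. Other settings also ended calls in these lists, with the highest adjusted p at STAB2, DES, RELN, LYZ, CD79A and KRT7 with the higher-scoring 50% of each peak list (0.0569, 0.281, 0.144, 0.274, 0.507 and 0.191), DCN without centring (0.111) and LUM with windows of 10 kb (0.599). In all, 7 lists rose and 0 fell with limma camera, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. The correlation estimated from the 4 libraries was 0.000232 for the NF-kB regulators, −0.134 for the CXC chemokines and −0.0543 for the immediate early factors. These values lie under the preset 0.01, so a higher correlation did not end those calls. The estimate was 0.475 for the other inducible chemokines, 0.0878 for the adhesion genes, 0.0670 for the cytokines and 0.0273 for the interferon genes. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries, and with the preset value from the number of genes. A call lost there therefore does not show that correlation among members was the cause.

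**Figure D3:**
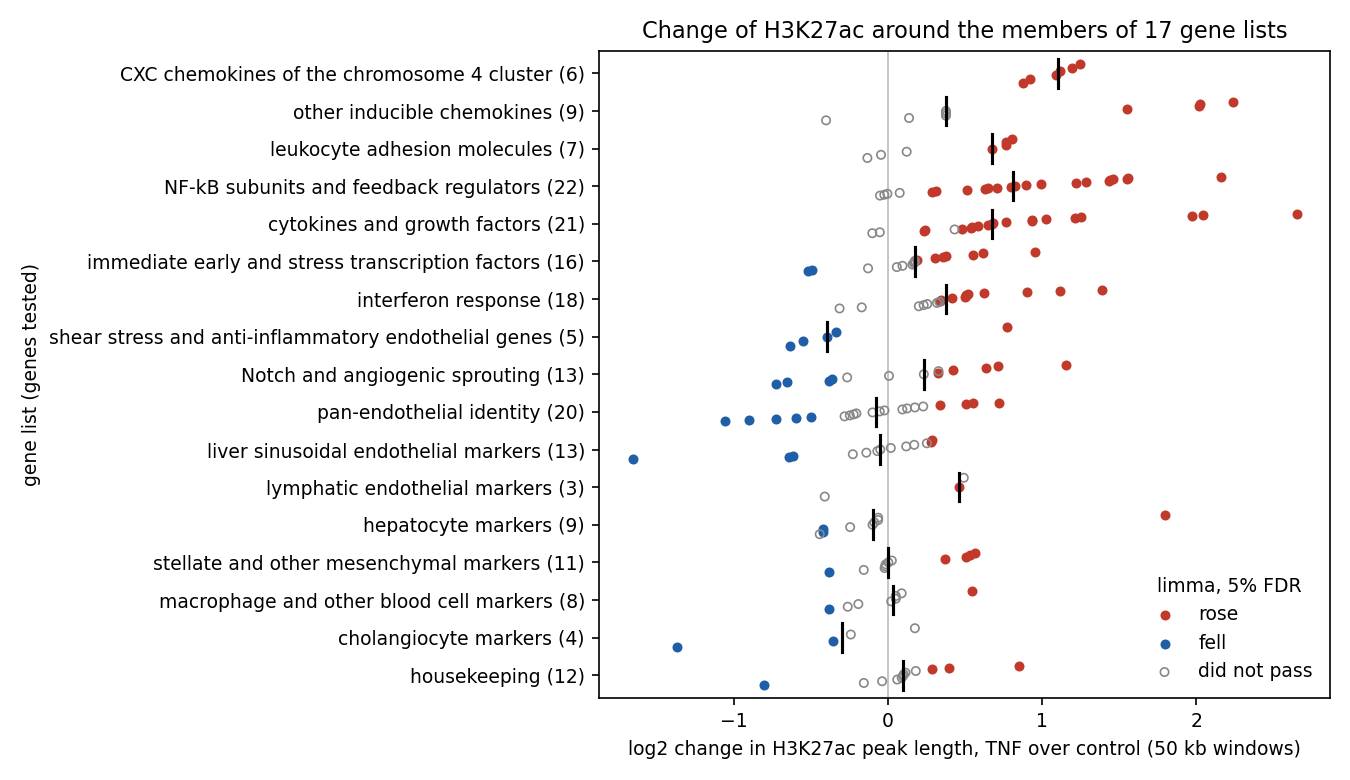
Log2 change of H3K27ac peak length, TNF over control, for each tested member of 17 gene lists, with members that rose in red, those that fell in blue, others open, and a black line at the list median. All 6 CXC chemokines and 18 of 22 NF-kB regulators rose, and members of the pan-endothelial list lie on both sides of 0.

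To ask which genes lay near newly acetylated regions, peaks were compared by presence and absence. Regions with a peak in both TNF libraries and neither control lay near all 6 CXC chemokines, 20 of 21 cytokine genes, 16 of 22 NF-kB regulators, 14 of 21 interferon genes and 11 of 16 immediate early factors, against 33.3% of the genes outside each list. Fisher exact adjusted p-values were 0.00779, 6.94e-08, 0.00268, 0.00862 and 0.0189. These tests count genes that share windows as separate, and the windows of the 6 CXC chemokines form 2 groups that do not overlap. The windows of the 21 cytokine genes tested with limma form 18 groups, and those of the 18 interferon genes form 13. Without TNF replicate 1, only the cytokine list passed, with adjusted p of 0.178 for the CXC chemokines, 0.0676 for the NF-kB regulators, 0.0732 for the interferon genes and 0.213 for the immediate early factors. Without TNF replicate 2 the CXC chemokines (0.249) and the immediate early factors (0.0905) did not pass, nor did the latter without control replicate 2 (0.0679), with the higher-scoring 50% of each peak list (0.723) or with peaks covering at least 50% of a region (0.220). The hepatocyte list passed with fewer gained regions without control replicate 1 (adjusted p = 0.0438) and with windows of 100 kb (0.0459). Gained regions that ranked high in both TNF lists lay within ZFAND3, DOCK10, EHMT1 and TEN1, and lost regions that ranked high in both control lists lay within CHN2, HSF2BP, MXRA7 and TCEA3. Genome-wide, 7314 regions were gained, 7340 were lost and 50137 were shared by the 4 libraries. The other 2 splits of the libraries, which put a control and a TNF library in each pair, gave between 1161 and 2669 regions in a direction. Gained regions numbered 11192 without control replicate 1, 17650 without TNF replicate 1 and 18255 without TNF replicate 2. Lost regions numbered 15308 without control replicate 1, 23047 without control replicate 2 and 11511 without TNF replicate 1.

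To relate NF-kB binding to the acetylation changes, NF-kB peaks of the TNF library were placed on the H3K27ac domains and regions. NF-kB peaks lay in 22.2% of the domains that rose (399 of 1799, 95% exact binomial interval 20.3% to 24.2%), 4.12% of those that did not pass (238 of 5771, 3.63% to 4.67%) and 1.28% of those that fell (22 of 1722, 0.802% to 1.93%). Against the domains that did not pass, the odds ratio was 6.63 for those that rose (Fisher exact p = 2.53e-107) and 0.301 for those that fell (Fisher exact p = 6.80e-10). Domains that rose were longer, with a median covered length of 5.59 kb against 3.65 kb for those that did not pass and 4.21 kb for those that fell. Pooled within 5 classes of mean covered length, the odds ratio for domains that rose was 4.97 (Mantel-Haenszel chi-square test, p = 3.13e-83), and within 5 classes of the length covered after TNF it was 3.97 (p = 1.68e-54). This comparison of domains was added after the data were seen, and it rests on 1 NF-kB library. Without TNF replicate 1, the odds ratio for domains that fell was 0.166, and without centring it was 0.177. With no minimum length, the odds ratio for domains that rose was 12.4.

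**Figure D4:**
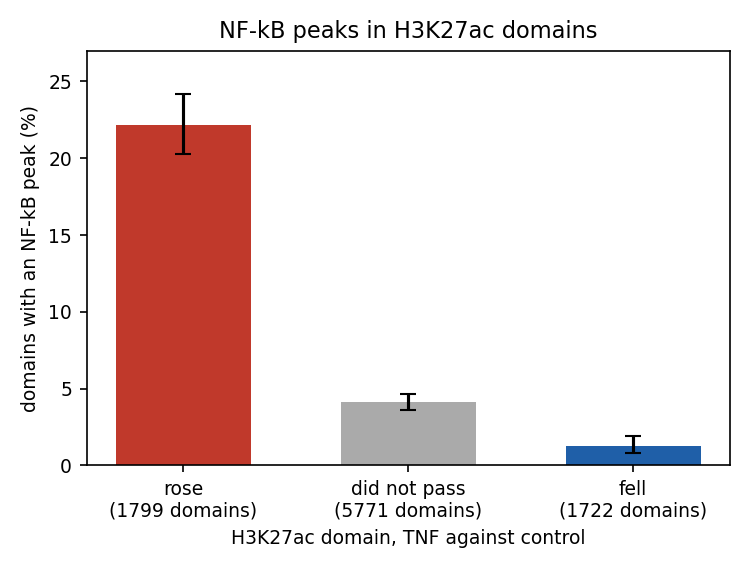
Share of H3K27ac domains with an NF-kB peak, in percent, for domains that rose, did not pass or fell after TNF, with 95% exact binomial intervals. The share is 22.2% among domains that rose and 1.28% among those that fell.

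After the peak at CXCL8, the NF-kB peaks with the highest scores lay in CD82 (108) and 0.0640 kb from SMPD1 (99.5). Peaks also lay 61.7 kb from NFKB1 (77.7) and in NFKB2 (75.5), both NF-kB subunit genes. The peaks 20.0 kb from LRRC32 (88.4) and in IL4I1 (66.9) were on gained H3K27ac regions alone. An NF-kB peak lay in the window of 18 of 22 NF-kB regulators, 7 of 10 other inducible chemokines, 4 of 6 CXC chemokines, 11 of 21 cytokine genes and 7 of 16 immediate early factors, against between 11.5% and 11.6% of the genes outside each list. Fisher exact adjusted p-values were 1.06e-12, 0.000139, 0.00759, 4.93e-05 and 0.00526, and with windows of 10 kb 3 lists passed, without the other inducible chemokines (adjusted p = 0.175) and the immediate early factors (0.0688). These tests count genes that share windows as separate. The windows of the 6 CXC chemokines form 2 groups that do not overlap, and those of the 9 other inducible chemokines tested with limma form 5. With the higher-scoring 50% of the NF-kB list 6 passed, the leukocyte adhesion genes among them (adjusted p = 0.0441, and 0.213 with the whole list). No shear stress gene (0 of 8) had one, and 2 of 21 pan-endothelial genes did (Fisher exact adjusted p = 1 for both lists).

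Single regions were compared in the same way. An NF-kB peak overlapped 129 of 7314 gained regions (1.76%, 95% exact binomial interval 1.47% to 2.09%), 715 of 50137 shared regions (1.43%, 1.32% to 1.53%) and 0 of 7340 lost regions, which by definition have no H3K27ac peak in TNF cells, where NF-kB was profiled. The odds ratio of gained against shared regions was 1.24 (Fisher exact p = 0.0287), but it was 1.10 without control replicate 1 (Fisher exact p = 0.275), 1.18 without control replicate 2 (Fisher exact p = 0.0709), 0.576 without TNF replicate 1 and 0.549 without TNF replicate 2. It was 2.42 with the higher-scoring 50% of each H3K27ac list and 2.49 with peaks covering at least 50% of a region. Gained regions were shorter, with a median of 460 bp against 1135 bp for shared regions. For a comparison by width, 5 classes were set over the widths of gained regions, 186 to 3713 bp, and shared regions outside that range were left out. Within these classes the odds ratios were 1.60, 8.25, 7.06, 6.11 and 3.78 from the narrowest to the widest, the first with a Fisher exact p of 0.572. The pooled odds ratio within these classes, a comparison added after the data were seen, was 4.19 (Mantel-Haenszel chi-square test, p = 1.48e-39). That value covers fewer shared regions than the odds ratio of 1.24. At most 1.31% of the shared regions in a class held an NF-kB peak, against 1.43% of all shared regions. The shared regions left out thus held one more often, and the odds ratios of 4.19 and 1.24 do not compare the same regions. The pooled odds ratio was 3.15 and 3.59 without control replicates 1 and 2, and 2.70 and 2.66 without TNF replicates 1 and 2. Per Mb of region, gained regions held 3.61 times as many with an NF-kB peak as shared regions. Of the 1153 NF-kB peaks, 54.9% and 50.5% overlapped H3K27ac in control replicates 1 and 2, 67.6% and 68.1% in TNF replicates 1 and 2, and 74.7% in any of the 4. Of all NF-kB peaks, 55.2% lay within protein-coding gene spans.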

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

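The tests on the 500 longest domains, of NF-kB peaks in domains and within classes of length or width, and with an estimated correlation plus replicate block were chosen only after the results were seen. Of the 500 longest domains 199 rose and 80 fell, and ranked by the control or the TNF libraries alone 154 and 108 or 247 and 54. Among domains, 3552 rose with no minimum length, 1106 with the higher-scoring 50% of each list and 741 with no stitching, and 869, 893 and 462 fell without centring, with the higher-scoring 50% and with no stitching. Among genes, 1460 rose without centring and 1677 with windows of 10 kb, and 1347, 1808 and 1535 fell without centring, with the higher-scoring 50% and with windows of 10 kb. With the higher-scoring 50% of each list, regions gained and lost numbered 4026 and 3777, the Jaccard difference was 0.0943 and the 4q13.3 ratio was 2.63. By construction other numbers of peaks, domains or genes enter these settings, except for centring. Without centring, the difference between the domain medians of control replicates 1 and 2 (4352 and 3638 bp) stays in the spread within the group. Whether this is the whole cause was not tested. With windows of 10 kb, 1 list was called lower by camera and 3 lists passed for NF-kB peaks. With an estimated correlation, 0 lists were called higher (3 at an unadjusted p under 0.05), and 0 with an estimated correlation and a replicate block. Leaving out 1 library gave 1340 to 1721 domains that rose, 1176 to 1375 that fell, 2200 to 2345 genes that rose, 1875 to 2242 that fell, 6 to 7 lists higher and 0 lower, 9110 to 18255 regions gained, 10691 to 23047 lost and 1 to 6 lists past 5% for gained regions, of which hepatocyte markers, without control replicate 1, had fewer. It gave odds ratios of 0.549 to 1.18 for NF-kB peaks on gained against shared regions, 6.50 to 6.78 for domains that rose and 0.166 to 0.320 for domains that fell, and a 4q13.3 ratio of 1.96 to 2.39. The first of these odds ratios was 1.10 and 1.18 without control replicates 1 and 2 and turned to 0.576 and 0.549 without TNF replicates 1 and 2, where regions need a peak in fewer libraries. Pooled within 5 classes of region width, without shared regions outside the widths of gained ones, it was 2.66 to 3.59 with 1 library left out. With other peak filters it was 4.16 to 5.34. With windows of 10 kb, the log2 change turned at ICAM5 (−0.35), VEGFC (−0.038), PDGFB (−0.22), IRF9 (−0.051), FCN3 (−0.23), CSF1R (−0.34), KRT7 (0.31) and PPIA (−0.23), and with windows of 100 kb at MMRN2 (0.10), and the cause was not tested. Of these, CSF1R alone then passed, as lower (limma adjusted p = 0.0194). The 25 domains with the largest rises and falls kept direction and side of the threshold in all 290 alternatives in which they were tested, and 11 of them were under the minimum length with the higher-scoring 50% of each list, 8 without TNF replicate 1 and 8 without TNF replicate 2. Of 35 long domains, whose alternatives were added after the results were seen, 9 lost the call in 26 alternatives and 4 passed in 5 where they had not, and with quantile normalization COL3A1 and COL5A2 (−0.017, adjusted p = 0.723) and COL6A3 and MLPH (−0.11, which then passed as lower, adjusted p = 0.0296) turned. Of the alternatives for single list genes, 2523 were the same, 116 weaker and 45 stronger. Same-numbered libraries deviated with a correlation of 0.0181 over domains and 0.00954 over genes, so no shared deviation was seen. No label says that the numbers mark pairs, and these values cannot exclude it. With the replicate block, 1887 domains rose and 1828 fell, and 2821 genes rose and 2920 fell, and no list call at the preset correlation changed. The peak lists give no depth, so changes in regions below the authors' threshold were not detectable. The motif search and its alternatives were not run, since no genome sequence was used here.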

Other observations

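The tests of additional gene lists, of marker genes in the control libraries, of domain length and of control replicate 1 were chosen only after the results were seen. A further 4 lists were written after the domain results were known, so their p-values describe lists picked with some knowledge of these data. Of 10 tested genes for inducible enzymes and complement, 8 rose and 0 fell (median log2 change 0.50, limma camera adjusted p = 2.63e-06, and adjusted p = 0.140 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase gene, rose by 1.23 and its window held 4 NF-kB peaks. NOD2, which encodes a receptor for bacterial wall fragments, rose by 1.59, CFB by 0.84 and NAMPT by 0.57. PTGS2, the gene of an inducible cyclooxygenase, rose from 1.33 kb ± 0.907 (SD, n = 2) to 3.95 kb ± 0.0785. Of 17 YAP and TEAD targets, 5 rose and 1 fell (camera adjusted p = 0.702). Of 10 matrix proteases and inhibitors, 3 rose and 1 fell (camera adjusted p = 0.702). SERPINB2 rose by 0.82 and TIMP3 by 0.80, and MMP2, a gelatinase gene, fell by 1.21.

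The fall at FKBP5, not called without centring (adjusted p = 0.0919), prompted a hypothesis that acetylation at glucocorticoid receptor targets falls with TNF, tested on a list without FKBP5. The test was undecided. Of 12 such genes, 3 rose and 3 fell, the median log2 change was −0.041, and limma camera gave an adjusted p = 0.870. TSC22D3 (−0.50), GLUL (−0.54) and PER1 (−0.24) fell, and KLF9 (0.25), DUSP1 (0.27) and CRISPLD2 (0.28) rose.

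In the control libraries, markers of mesenchymal cells carried more H3K27ac than endothelial markers. Counted over gene spans with 2 kb either side, the median of 12 mesenchymal genes was 16.6 kb and that of 22 pan-endothelial genes 1.96 kb (ratio 8.43, permutation p = 0.0201), and as a percent of the span 29.7% against 2.80% (ratio 10.6, permutation p = 0.00584), which argues against neighbouring genes or longer genes as the source. COL1A1, COL1A2 and COL3A1 had 21.1, 35.5 and 38.4 kb, while 3 of 16 liver sinusoidal markers, GATA4 (50.5 kb), MRC1 (2.71 kb) and CD36 (0.524 kb), had any, and STAB1, STAB2, LYVE1, TIE1, CLDN5 and EGFL7 had none. Of 22 pan-endothelial genes, 16 had some H3K27ac in the span. So did 5 of 6 cholangiocyte, 7 of 15 hepatocyte and 5 of 11 macrophage and blood cell markers, so this does not show endothelial cells. If the cultures hold endothelial cells, mesenchymal cells beside them, or a mesenchymal programme in them, may both be the source. These cannot be told apart in lists from whole cultures. ETS1, FLI1 and ENG held the most of the pan-endothelial genes, and no biological explanation was tested. The identity of the purchased cells was not tested separately and stays open, so values given for LSEC describe cultures labelled as LSEC.

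Domains that fell held few NF-kB peaks. Within 5 classes of mean covered length the pooled odds ratio against domains that did not pass was 0.263 (Mantel-Haenszel chi-square test, p = 4.21e-10), and within 5 classes of the length covered after TNF it was 0.310 (p = 9.12e-08), which argues against short domains as the whole cause. Of the domains that fell, 63.9% kept direction and passed 5% without control replicate 1, the library with the longest called length. This was the lowest share among the libraries left out in turn. Of the 1722 domains, 1518 were still tested and 0 changed direction. Without centring, 50.5% of the falls were kept. The falls were selected with control replicate 1 in the fit, and leaving it out left a lone control library. The share therefore cannot decide whether that library was the cause, which stays open. A TNF-dependent loss of acetylation away from NF-kB sites may be considered as a hypothesis, found and tested on the same libraries, and differences in depth between the groups stay open.

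Of the 1153 NF-kB peaks, 292 overlapped no H3K27ac peak. A candidate explanation is that NF-kB sits in gaps between acetylated nucleosomes. Of these 292 peaks, 56.2% lay within 500 bp of an H3K27ac peak, against 4.71% of positions shifted by 50 kb (odds ratio 25.9, Fisher exact p = 1.56e-63), and 112 had one on both sides. Sites beside acetylated sequence, without a gap, would also lie closer than shifted positions, so the comparison does not single out gaps. In addition, 104 peaks bridged at least 2 regions. With H3K27ac regions extended by 500 bp, an NF-kB peak lay on 4.79% of gained, 2.04% of shared and 0.0136% of lost regions. These shares were not matched for width, and an extended region can take in a peak on a neighbouring region. Lost regions by definition have no H3K27ac peak in TNF cells, where NF-kB was profiled.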
